A study of Mus musculus with 2 samples.

How the data were processed

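DNase-seq peak calls from intestine of mouse embryos at embryonic day 14.5 were used for 2 biological replicates, which formed 1 group with the replicate numbers the labels give. Each replicate had its own biosample record, and both pointed to the same strain record; p-values therefore rest on genes or regions within these 2 libraries and not on animals. Per the labels, the build is mm10, and per the deposited readme text each file was made from 1 replicate without pooling. The aligner, the callers, their thresholds and filters, and the read depth are not given in the sources used here.

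For each replicate 6 files were used. The signal in the 2 peak lists from the first set of alignments is deposited without a stated normalization. Its values were whole multiples of a single step in each replicate (tolerance 0.05 steps), 0.00381 in replicate 1 and 0.00412 in replicate 2, a ratio of 1.08. What the step stands for is not stated and was not tested, so depth cannot be read from it, and no counting interval was given. The third peak list, from other alignments, carries a whole-number score per peak whose making the authors do not describe in the sources used here. The deposited hotspots carry −log10 of a q-value, per the broadPeak layout named in the readme text, and a score of 10 times that value. The authors' file of false discovery rates, a p-value-like FDR per run of positions, lists only positions under 0.05, and the deposited footprints all carry the same FDR value, 0.01. A second file of false discovery rates per replicate, made from the alignments of the hotspots, was not used.

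The readme text tied no peak list to both hotspots and footprints, so the list with the middle number of peaks was taken in both replicates, as fixed beforehand. Every peak of this list held a position at a false discovery rate under 0.05, and every peak of the shorter list a position under 0.001. The gene lists, motifs, tests, named-gene rule and most alternatives were fixed before the data were examined. Gene models were GENCODE vM21 basic on GRCm38.p6, with 21911 coding gene symbols on 21 chromosomes. There were 25 gene lists with 278 genes, of 4 to 20 genes each.

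Peaks were shared when they overlapped by at least 1 bp, and chance was measured with 20 circular shifts within chromosomes. A promoter peak had any of its bases within 500 bp of a transcription start site, and promoter signal was the highest signal there. The shares of all peaks at promoters, exons, introns and intergenic sequence instead went by the peak midpoint. Promoter lists were tested with Fisher's exact test, two-sided, against all other coding genes. Distal lists were tested with 10000 random lists matched on deciles of window length, the window being the gene body and 20 kb on each side without promoter regions. The replicate difference was the median log2 ratio of signal at shared regions in the gene body and 20 kb on each side, promoter regions included, centred on the median of all shared regions, against 10000 random lists matched on deciles of mean signal. Benjamini-Hochberg adjustment ran over the 25 lists in each test with a threshold of 0.05, and the smallest p that the random lists can give is 0.0002. For 32 consensus motifs, matches on either strand were counted in 150 bp windows at peak centres and in windows 2 kb to each side that touched no peak. Footprints were used as called.

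The genes named were, per list, the 3 members with the highest mean promoter signal, the 2 with the most distal shared regions and up to 3 in alphabetical order without a promoter peak in either replicate. Added to these were the 10 coding genes with the most distal regions and the 5 shared promoter peaks of above-median signal with the largest ratio in each direction. The motifs named were the 6 highest and 3 lowest by fold at distal peaks and CDX, HNF4, GATA, FOX and CTCF. Hox genes were described one by one, and names outside the rule were chosen after their values were seen. Some genes that the rule names are not reported here.

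The alternatives fixed beforehand were the other peak lists, the strongest 50000 peaks, an overlap of at least 50% of both peaks, promoter widths of 1000 bp and 2500 bp, windows of 5 kb and 50 kb, no matching of random lists, quantile normalization, hotspot values in place of peak signal, regions above the median signal, 300 bp motif windows, GC-matched background windows, the reversed consensus, and each replicate left out. Alternatives added after seeing the data were a signal floor of 0.25, a ratio adjusted for GC content in 50 bins, the replicate difference away from promoters, and random lists also matched on CpG-dense sequence, defined in 200 bp bins by a GC content of at least 55% and an observed to expected CpG ratio of at least 0.65.

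The overlap, list and motif statistics were tested on simulated data. A simulated overlap of 60% was recovered as 60%, and a simulated doubling of signal as a log2 ratio of -1. Of 20 simulated lists of 15 genes with 2.5 times the distal regions, 65% were called, against 3% of 200 unchanged lists at an unadjusted p under 0.05. Of 20 lists with peaks at 20% of promoters 100% were called, against 5% of 200 unchanged lists. Of 10 lists shifted by 0.15 on the log2 scale 90% were called, against 6.67% of 60 unchanged lists, and every implanted motif was found. All these list calls were at an unadjusted p under 0.05. The log2 ratios were first shuffled over regions, which removes any likeness of neighbouring regions. Distal counts and promoter peaks were drawn for each gene on its own, so neighbouring genes with shared windows were not copied. The rates of all 3 list tests therefore need not hold for the reported calls. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.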

Results

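Chromatin accessibility was mapped by DNase-seq, in which DNase I cleaves exposed DNA in nuclei, in the intestine of B6NCrl mouse embryos of both sexes at embryonic day 14.5. The 2 libraries were biological replicates from separate biosamples and formed 1 group, so the data describe 1 tissue and the difference between its replicates, without a contrast of conditions. All positions are in mouse build mm10, and values are given as mean ± SD with n = 2 unless the replicates are named. The signal of a peak is the authors' own value, on a scale whose normalization is not given in the sources used here, and read depth is unknown. Signal values were whole multiples of a step of 0.00381 in replicate 1 and 0.00412 in replicate 2.

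Housekeeping promoters were among the most accessible. The promoter of Rplp0, which encodes a ribosomal protein (chromosome 5, 115559467 to 115563727), had a peak signal of 7.69 ± 0.394, and that of the cyclophilin gene Ppia (chromosome 11, 6415443 to 6419817) had 6.72 ± 0.901. Of 21911 protein-coding genes, 14772 (67.4%) had a peak within 500 bp of a transcription start site in both replicates. Another 348 genes had a promoter peak in replicate 1 only and 349 in replicate 2 only. By peak midpoint, promoters held 15.1 ± 2.59% of peaks, 6.62 ± 1.14 times their share of the genome. Exons held 6.17 ± 0.0903% of peaks (1.92 ± 0.0281 times their genome share), introns 42.8 ± 1.295% (1.03 ± 0.0313 times) and intergenic sequence 35.96 ± 1.39% (0.676 ± 0.0261 times). Within 2500 bp of a start site the promoter share was 31.6 ± 4.03%. Replicate 1 had 208181 peaks covering 46.0 Mb and replicate 2 had 151122 peaks covering 36.6 Mb, with a median width of 200 bp in each. The deposited hotspots, which are broader accessible regions called from other alignments, numbered 183172 and 134513. The shorter deposited list from the same alignments held 135539 and 87917 peaks.

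Away from promoters, a coding gene had a mean of 3.15 and a median of 2 shared accessible regions in its body and the 20 kb on each side, and 5408 genes had none. The largest counts were 302 for Gm20388 and 117 for Fgfr2, a fibroblast growth factor receptor gene, whose annotated spans on chromosomes 8 (119910841 to 124345722) and 7 (130162451 to 133123350) both reach across neighbouring genes. The RNA-binding protein gene Rbms3 had 59 regions and the transcription factor gene Zfhx3 had 58. Camta1, a calmodulin-binding transcription activator gene, had 57, and the phosphodiesterase gene Pde4d had 53. The potassium channel gene Kcnq1 followed with 45 regions, Nav2 with 44, Gm37240 with 43 and Etl4 with 42. Counting only peaks with a signal of at least 0.25, Kcnq1 had 22 regions, Etl4 had 23 and Rbms3 had 36.

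To ask how far the replicates resembled each other, their peaks were compared by position. Peaks of high signal were mostly called in both libraries, and peaks of low signal mostly in 1. Of replicate 1 peaks, 46.2% overlapped a replicate 2 peak, and 62.3% of replicate 2 peaks overlapped a replicate 1 peak, against 2.58% and 3.46% for peaks shifted along the chromosomes. In the decile of highest signal 98.8% and 99.5% of peaks were shared, and in the lowest decile 2.67% and 22.9%. Across 84138 shared regions the signals had a Spearman rho of 0.956, where regions are not independent replicates, and the median log2 ratio of replicate 1 to replicate 2 was -0.21. The bases of the 2 peak lists had a Jaccard index of 0.336. Private peaks numbered 112093 in replicate 1 and 57023 in replicate 2, with a median signal of 0.141 and 0.296 against 0.648 and 0.745 for shared peaks. Counted by any base of the peak rather than its midpoint, promoters made up 4.89% and 6.19% of private peaks and 27.5% of shared peaks in both replicates. Only 9.41% of replicate 1 private peaks and 15.4% of replicate 2 private peaks held a position listed in the other replicate's file of false discovery rates. Requiring an overlap of at least 50% of both peaks lowered the mean shared percentage from 54.2 ± 11.4 to 35.8 ± 8.06, and the strongest 50000 peaks raised it to 89.3 ± 0.693. Here the SD is over the 2 directions of 1 overlap. It depends on how the 2 lists differ in length and does not measure the spread of reproducibility.

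**Figure D1:**
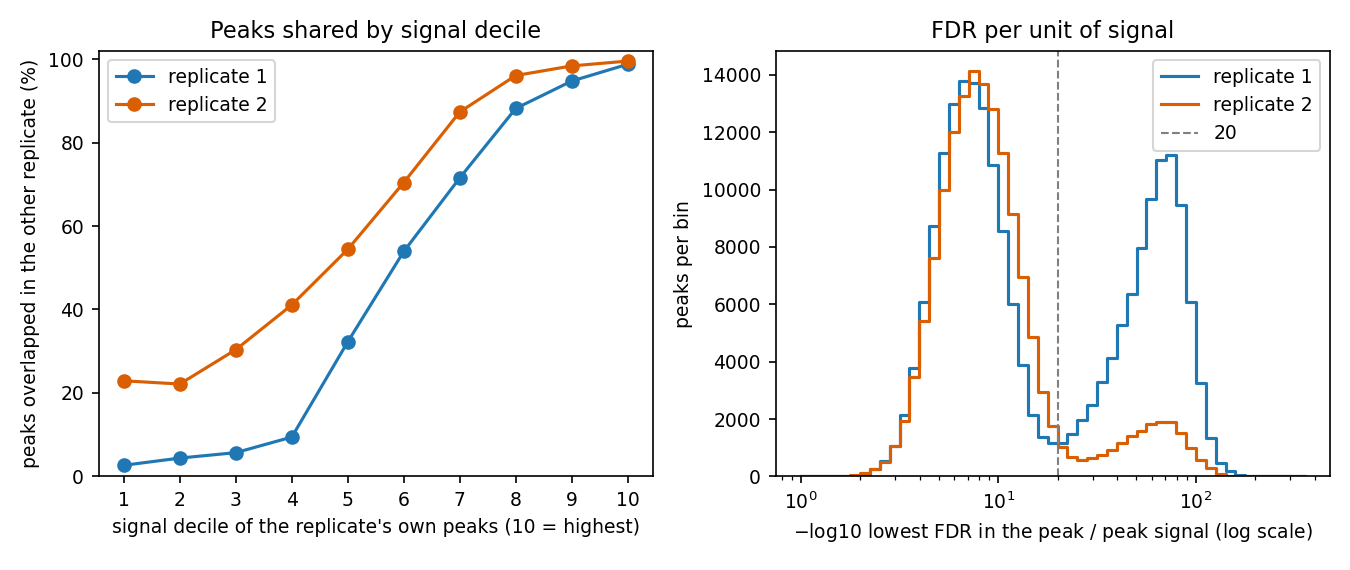
Left, percentage of each replicate's peaks overlapped in the other, by decile of signal, which runs from 2.67% and 22.9% in the lowest decile to 98.8% and 99.5% in the highest. Right, number of peaks by −log10 of the lowest false discovery rate in the peak divided by its signal, on a log axis with a dashed line at 20, beyond which lie 41.7% of replicate 1 and 11.8% of replicate 2 peaks.

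Peaks of replicate 1 included a large class with low signal and very low false discovery rate. This class, defined after the values were seen as peaks whose −log10 of the lowest false discovery rate was at least 20 times their signal, held 86862 peaks (41.7%) in replicate 1 and 17829 (11.8%) in replicate 2. Their median signal was 0.114 and 0.119, against 0.518 and 0.519 for the other peaks. They lay in runs along the chromosomes: the next peak was also of this class in 91.7% and 82.2% of cases, and 2652 and 527 runs had at least 10 such peaks. On chromosome X the class made up 12.2% and 7.51% of peaks, and on the autosomes 42.3% and 11.9%. Of these peaks 10.7% in replicate 1 and 35.9% in replicate 2 were shared, against 71.6% and 65.8% of the others. This comparison was not matched on signal, and the low signal of the class is partly built into its definition. Among all peaks of the lowest signal decile 2.67% and 22.9% were shared. Whether the class was shared less often than other peaks of like signal was not tested.

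Promoters of 25 gene lists, fixed before the data were examined, were compared with all other coding genes by Fisher's exact test, two-sided, adjusted over the lists. The gut mesenchyme list was accessible at all 17 of its promoters (adjusted exact p = 0.0124), among them Nkx2-3, a homeobox gene of gut mesoderm (chromosome 19, 43612325 to 43615892), at 4.39 ± 0.931. In the same list the hedgehog effector Gli1 (chromosome 10, 127329882 to 127341974) had a signal of 2.70 ± 0.335 and the growth factor receptor gene Pdgfra (chromosome 5, 75152292 to 75198215) had 2.69 ± 0.354. Blood and immune genes had peaks at 3 of 13 promoters (adjusted exact p = 0.0124), among them those of the blood regulators Tal1 (2.12 ± 0.275) and Runx1 (1.73 ± 0.545). No peak was found at Adgre1, Csf1r or Gata1, genes of macrophages and erythroid cells. Genes of germline, retina and epidermis had a peak at 1 of 12 promoters (adjusted exact p = 0.00092), the keratin gene Krt10, at 2.29 ± 0.396, and none at the retinal gene Crx, the germ cell gene Ddx4 or the epidermal gene Flg. With an overlap of at least 50% of both peaks, the gut mesenchyme share was 88.2% and its adjusted exact p 0.0640.

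The other 22 lists had adjusted p values from 0.0752 to 1. Of 8 alternatives, 1 called the intestinal epithelial regulators higher (peaks within 1000 bp, adjusted exact p = 0.0468, range 0.0468 to 0.632) and 1 called smooth muscle higher (50% overlap, adjusted exact p = 0.0239, range 0.0239 to 0.543). All 20 intestinal epithelial regulators had a promoter peak in at least 1 replicate and 18 had it in both, with Ehf covered in replicate 1 only and Cdx1 in replicate 2 only, names chosen after their values were seen. Klf5, a transcription factor of crypt epithelium (chromosome 14, 99298691 to 99315036), had a signal of 2.37 ± 0.337, and the progenitor factor Sox9 (chromosome 11, 112782224 to 112787760) had 1.97 ± 0.236, with Gata6, an endoderm factor, at 1.88 ± 0.0433. Of 15 genes of epithelial structure 13 had a promoter peak in both, with the protease inhibitor gene Spint2 at 2.20 ± 0.148, the adhesion gene Epcam (chromosome 17, 87635979 to 87651129) at 1.61 ± 0.0439 and E-cadherin, Cdh1 (chromosome 8, 106603351 to 106670246), at 1.46 ± 0.122, and none at the galectin gene Lgals4. Wnt targets and stem cell genes had 11 of 12, led by the Wnt feedback genes Znrf3 (chromosome 11, 5276324 to 5444847) at 6.85 ± 1.05, Nkd1 at 4.56 ± 0.542 and Rnf43 at 3.27 ± 0.206, with no peak at the crypt marker Olfm4. Secretory and enteroendocrine genes had 9 of 13, with the granule protein gene Chga at 3.62 ± 0.548, the Notch ligand gene Dll1 at 1.73 ± 0.0625 and the secretory fate gene Atoh1 at 1.35 ± 0.0876, and without peaks at the mucin gene Muc2, Pax4 or Spdef. Mature enterocyte genes had 7 of 12, with the lipid transfer gene Mttp at 4.75 ± 0.309, the aminopeptidase gene Anpep at 1.44 ± 0.213 and the glucose transporter gene Slc5a1 at 0.545 ± 0.0157, and without peaks at the apolipoprotein genes Apoa1 and Apoa4 or the lactase gene Lct. In the shorter peak list and among the strongest 50000 peaks only 2 of the 12 (16.7%) had a peak, and the list was called lower (adjusted exact p = 0.0139 and 0.0168, range over 8 alternatives 0.0139 to 1).

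Among lists of the gut wall, smooth muscle had 11 of 11 promoters with a peak, including the contractile genes Smtn (2.43 ± 0.645) and Myh11 (2.16 ± 0.238) and the actin-binding gene Synpo2 (1.52 ± 0.478). The enteric nervous system had 14 of 15, with the neuronal RNA-binding gene Elavl4 at 3.11 ± 0.0941, Tlx2 at 2.19 ± 0.279 and Hand2 at 2.19 ± 0.0521. Interstitial cells of Cajal, the gut pacemaker cells, had 4 of 4, with the receptor gene Kit at 2.69 ± 0.780, Etv1 at 2.18 ± 0.519 and Gpr20 at 1.17 ± 0.302. Endothelium had 9 of 12, with Egfl7 at 2.29 ± 0.514, the VEGF receptor genes Kdr at 1.87 ± 0.595 and Flt1 at 1.49 ± 0.123, and none at Cdh5 or Tie1. Mesothelium had 6 of 7, with Wt1 at 1.35 ± 0.0413, Bnc1 at 1.03 ± 0.185 and Upk1b at 0.667 ± 0.146, and none at Msln.

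Among lists of other organs none passed the threshold, but some did under an alternative. In the shorter peak list, liver (adjusted exact p = 0.0420), heart (0.0380) and skeletal muscle (0.0272) were called lower, and among the strongest 50000 peaks liver (0.0179) and heart (0.0479) were. Over 8 alternatives the adjusted exact p ran from 0.0179 to 0.439 for liver, 0.0380 to 0.744 for heart and 0.0272 to 0.394 for skeletal muscle. Stomach genes had 3 of 8, at Sox2 (1.60 ± 0.194), Barx1 (1.32 ± 0.0429) and Tff2 (0.749 ± 0.0884), and none at Gkn1, Gkn2 or Nkx6-3. Pancreas genes had 4 of 9, with the transcription factor genes Nkx6-1 at 1.77 ± 0.0913, Mnx1 at 1.43 ± 0.00315 and Pdx1 at 0.753 ± 0.0130, and none at the enzyme gene Cpa1 or the hormone genes Gcg and Ins1. Liver genes had 3 of 9, led by Cebpa at 4.38 ± 0.502 and including Ttr (0.557 ± 0.0388) and Serpina1a (0.321 ± 0.0175), and none at the plasma protein genes Afp, Ahsg and Alb. Lung genes had 2 of 6, the ciliated cell factor Foxj1 at 5.91 ± 1.07 and Nkx2-1 at 1.04 ± 0.0102, and none at the secreted protein genes Scgb1a1, Sftpa1 and Sftpb. Kidney and gonad genes had 5 of 7, with Six2 at 1.56 ± 0.315, Lhx1 at 1.39 ± 0.252 and Nr5a1 at 1.25 ± 0.102. Heart genes had 3 of 7, with Hand1 at 1.31 ± 0.147, Tbx5 at 0.646 ± 0.0572 and Nkx2-5 at 0.536 ± 0.0240, and none at the myosin genes Myh6 and Myh7 or at Nppa. Skeletal muscle genes had 3 of 8, with Pax3 at 1.16 ± 0.111, Pax7 at 0.938 ± 0.130 and Myod1 at 0.777 ± 0.0444, and none at Acta1, Ckm or Myf5. Brain genes had 8 of 10, with Gbx2 at 1.58 ± 0.139, Pax6 at 1.42 ± 0.220 and Otx2 at 1.37 ± 0.106, and none at Neurod6. Housekeeping genes had 12 of 12 (adjusted p = 0.0752, Fisher's exact test), and their median promoter signal of 4.86 lay at the 100th percentile of random lists. The percentile was 77.4 for Wnt targets and stem cell genes, 55.3 for gut mesenchyme, 53.5 for interstitial cells of Cajal and 42.2 for the enteric nervous system. It was lower for the other lists of epithelium and gut wall: 31.7 for intestinal epithelial regulators, 30.8 for epithelial structure, 29.2 for smooth muscle, 22.5 for mesothelium, 15.8 for secretory genes, 15.7 for endothelium, 8.76 for mature enterocytes and 2.81 for blood and immune genes. Lists of other organs lay between 2.74 for stomach and 34.9 for kidney and gonad. Germline, retina and epidermis lay at 1.84, and the Hox groups 1 to 4, 5 to 8 and 9 to 13 at 35.5, 57.2 and 31.5. Housekeeping genes were called higher at promoters under 3 of 8 alternatives, with an adjusted exact p from 0.0205 to 0.0841.

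Distal regions were counted per gene and compared with 10000 random lists matched on window length by a permutation test, two-sided, adjusted over the 25 lists, in which the smallest p possible was 0.0002. In this measure 11 lists had more regions than random lists and none had fewer. Genes of epithelial structure had a mean of 6.93 regions per gene against 2.501 in random lists, a ratio of 2.77 (adjusted permutation p = 0.001), with 34 regions at the intestinal cadherin gene Cdh17 (chromosome 4, 11758147 to 11817895) and 10 at the keratin gene Krt8. Gut mesenchyme had 10.1 against 3.68, a ratio of 2.73 (adjusted permutation p = 0.0125), with 30 regions at the homeobox gene Meis1 (chromosome 11, 18879817 to 19018985) and 17 at the hedgehog effector Gli2. Intestinal epithelial regulators had 7.15 against 3.20, a ratio of 2.23 (adjusted permutation p = 0.0125), with 17 regions at the endoderm factor gene Gata4 (chromosome 14, 63198922 to 63271692) and 16 at Shh, which encodes the signal sent from gut epithelium to mesenchyme. Of these regions, 7 at Cdh17 and 7 at Shh remained when only peaks with a signal of at least 0.25 were counted.

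The brain list had 9.20 regions per gene against 2.21, a ratio of 4.17 (adjusted permutation p = 0.001), with 21 at the eye and brain factor gene Pax6 (chromosome 2, 105668900 to 105697364) and 15 at Emx2. Kidney and gonad genes had a ratio of 2.91 (adjusted permutation p = 0.00917), with 13 regions at Six2 and 12 at Pax8. Skeletal muscle genes had a ratio of 2.35 (adjusted permutation p = 0.0325), with 23 at Pax3 and 9 at Pax7, and pancreas genes 2.32 (adjusted permutation p = 0.0327), with 13 at Nkx6-1 and 10 at Mnx1. Housekeeping genes had a ratio of 2.07 (adjusted permutation p = 0.0325), with 10 regions at the actin gene Actb. Of 11 alternatives, the call was lost under 8 for pancreas, 6 each for skeletal muscle and housekeeping and 2 for kidney and gonad, with adjusted p values up to 0.245, 0.464, 0.245 and 0.0908. Replicate 2 peaks alone gave adjusted p values of 0.158 for pancreas and 0.0708 for housekeeping, and replicate 1 peaks alone gave 0.163 for pancreas, 0.464 for skeletal muscle and 0.233 for housekeeping. With random lists also matched on CpG-dense sequence, an alternative added after the data were seen, the brain ratio was 2.17 (adjusted permutation p = 0.00625) and 3 calls were lost: kidney and gonad at 1.70 (adjusted permutation p = 0.0908), pancreas at 1.72 (0.0908) and skeletal muscle at 1.61 (0.106). The others kept their calls under this matching, with ratios of 2.38 for epithelial structure (adjusted permutation p = 0.00167), 1.90 for gut mesenchyme (0.049995), 1.66 for intestinal epithelial regulators (0.0487) and 1.91 for housekeeping (0.0487). How closely the random lists matched in CpG-dense sequence was not measured.

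The remaining lists did not pass. The ratio was 2.17 for heart (11 regions each at Nkx2-5 and Tbx5), 2.14 for lung (8 each at Nkx2-1 and Scgb1a1), 1.87 for secretory and enteroendocrine genes (8 each at Insm1 and Nkx2-2) and 1.85 for stomach (12 at Barx1 and 5 at Nkx6-3). It was 1.77 for smooth muscle (28 at Synpo2 and 6 at the muscle regulator Myocd), 1.62 for the enteric nervous system (19 at Hand2 and 10 at the neural crest gene Foxd3), 1.31 for mesothelium (7 at Upk1b and 6 at Wt1) and 1.23 for Wnt targets and stem cell genes (10 each at the stem cell marker Lgr5 and Sp5). Ratios nearer to 1 were found for interstitial cells of Cajal at 1.20 (14 regions at the chloride channel gene Ano1 and 5 at Gpr20), endothelium at 1.13 (11 at Erg and 10 at Pecam1), blood and immune genes at 1.09 (14 at Runx1 and 12 at Cx3cr1) and mature enterocytes at 1.01 (9 at Mttp and 8 at Fabp2). Genes of germline, retina and epidermis had a ratio of 0.681, with 4 regions each at Krt1 and Zp3, and liver genes 0.626, with 4 at Tat and 3 at Cebpa. Adjusted p values of these 14 lists ran from 0.0546 to 0.940 by the permutation test. Of 11 alternatives, 5 called heart higher (adjusted permutation p from 0.0156 to 0.297 over the 11), 4 secretory genes (0.00833 to 0.442), 2 smooth muscle (0.0322 to 0.420) and 1 lung (0.0415 to 0.487). Among these, replicate 2 peaks alone gave calls for secretory genes (2.13, adjusted permutation p = 0.0245) and heart (2.36, adjusted permutation p = 0.0409), and replicate 1 peaks alone for smooth muscle (2.58, adjusted permutation p = 0.0322). At a signal of at least 0.25 the regions numbered 13 at Synpo2, 10 at Hand2, 6 at Sp5, 3 each at Upk1b and Fabp2 and 2 at Mttp.

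**Figure D2:**
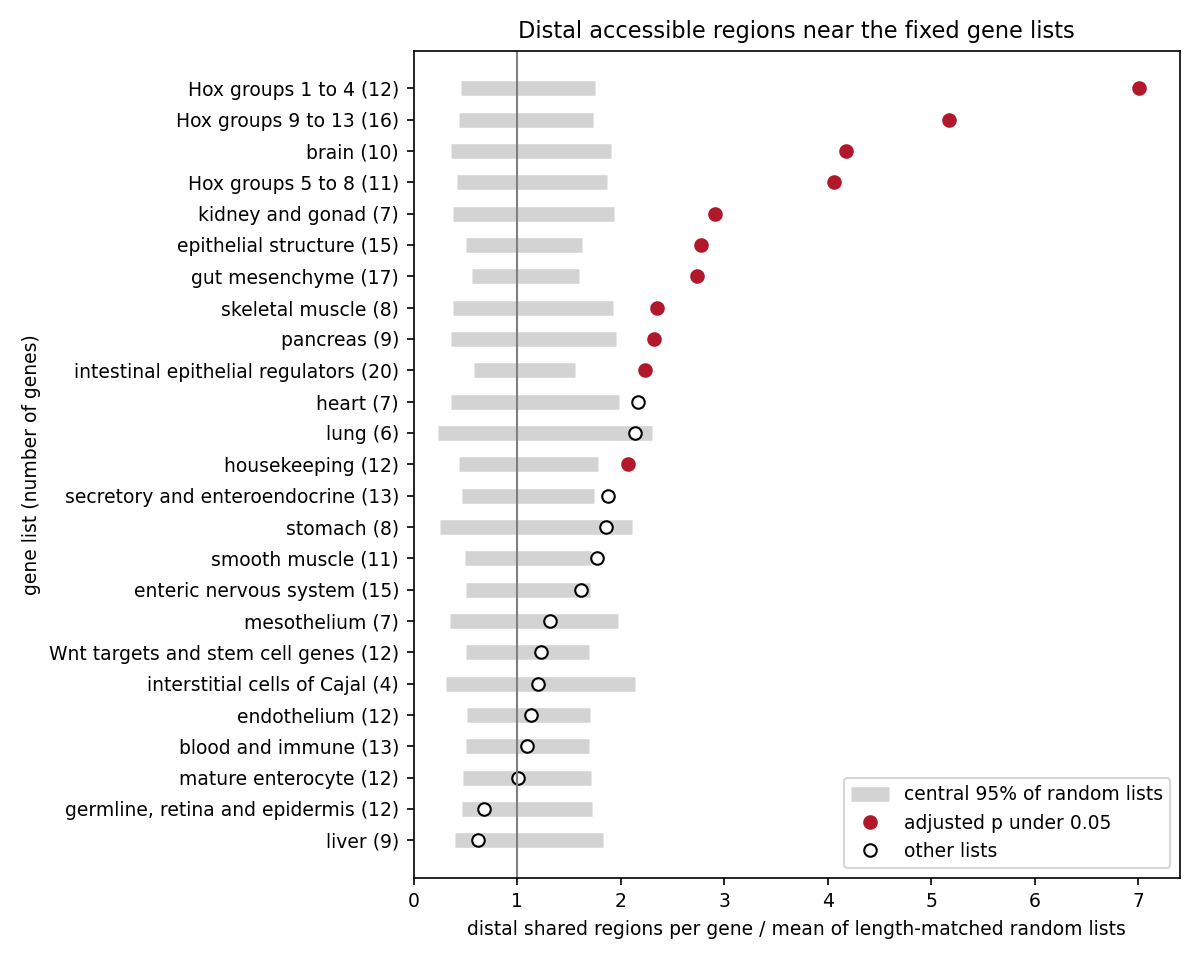
Distal shared regions per gene of each list divided by the mean of random lists matched on window length (points, filled where the adjusted p lay under 0.05), with the central 95% of random lists as grey bars and the number of genes in brackets. Hox groups 1 to 4 stand at 7.004, brain at 4.17 and epithelial structure at 2.77, while liver stands at 0.626.

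The Hox genes, whose order along each cluster follows the head-to-tail axis, were examined gene by gene because they set regional identity along the gut. Of 39 Hox genes, 32 had a promoter peak in both replicates. Hoxa3, Hoxb4, Hoxb13 and Hoxd12 had it in replicate 1 only, Hoxc4 and Hoxc12 in replicate 2 only, and Hoxb9 in neither. By cluster, both replicates covered 10 of 11 genes in A, 7 of 10 in B, 7 of 9 in C and 8 of 9 in D. The highest promoter signals were those of Hoxa5 (chromosome 6, 52201754 to 52204587) at 4.33 ± 1.08 and Hoxb5 (chromosome 11, 96303336 to 96306121) at 3.86 ± 0.420. Hoxa4 followed at 3.04 ± 0.267 and Hoxc10 at 2.99 ± 0.396, and Hoxa7 had 2.12 ± 0.222. Hoxa10 had 1.11 in replicate 1 and 3.40 in replicate 2. By paralogue group, both replicates covered 9 of 12 promoters of groups 1 to 4 (Fisher's exact test, adjusted p = 0.828), 11 of 11 of groups 5 to 8 (adjusted p = 0.0859, and 0.0326 to 0.900 over 8 alternatives, of which 1 gave a call) and 12 of 16 of groups 9 to 13 (adjusted p = 0.719). Distal regions in these groups were 7.004, 4.06 and 5.17 times those of random lists (permutation test, adjusted p = 0.001 each), with 28 at Hoxd3, 26 at Hoxa3, 11 each at Hoxb5 and Hoxc5, 21 at Hoxd13 and 17 at Hoxd12. With random lists also matched on CpG-dense sequence the ratios were 3.56, 1.93 and 2.33 (permutation test, adjusted p = 0.00167, 0.0130 and 0.00167). The windows of the 3 groups held a mean of 11.3, 12.5 and 10.6 CpG-dense bins, against 1.66 for all coding genes. The bins of the random lists were not measured, so CpG-dense sequence stays open as a part or the whole of the cause. Neighbouring Hox genes share windows, so their counts are not independent, and with an overlap of at least 50% of both peaks only 18 Hox promoters were covered in both replicates. With peaks within 1000 bp of a start site 35 were covered in both, so the count also depends on the promoter width.

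The difference between the replicates was measured as the log2 ratio of replicate 1 to replicate 2 signal at shared regions in the genes and the 20 kb on each side, promoters included, centred on the median of all shared regions, which describes these 2 libraries only. Regions of epithelial structure genes had a median of 0.15 (permutation test on random lists matched on signal, adjusted p = 0.0150), with 98 of 140 regions above 0. Hox groups 9 to 13 had a median of 0.13 (permutation test, adjusted p = 0.0300), with 86 of 128 regions above 0. These regions come from a few clusters with shared windows, which the random lists do not copy, so this p may be too small. The other 23 lists did not pass, among them mature enterocytes at 0.17 (adjusted permutation p = 0.184), intestinal epithelial regulators at 0.11 (adjusted permutation p = 0.152), secretory genes at 0.08, Wnt targets and stem cell genes at 0.02, gut mesenchyme at -0.03 and Hox groups 1 to 4 at -0.04. Among the lists that did not pass were also heart at 0.14, skeletal muscle at 0.13, brain at 0.10 and endothelium at 0.10, of which the first 3 turned below 0 with the hotspot values (-0.03, -0.33 and -0.10). These calls depended on the measure: with the hotspot values, which are −log10 of q, epithelial structure had 0.03 (adjusted permutation p = 0.831), Hox groups 9 to 13 had 0.23 (adjusted permutation p = 0.313) and epithelial regulators turned to -0.13. Called higher with these values were gut mesenchyme, which turned to 0.43, and pancreas at 0.72 (adjusted permutation p = 0.0450 each). Among regions above the median signal, epithelial structure had 0.13 and was no longer called (adjusted permutation p = 0.0517), while epithelial regulators were called at 0.15 (adjusted permutation p = 0.0350), as they were after quantile normalization at 0.11 (adjusted permutation p = 0.0417). Over 6 alternatives the adjusted permutation p ran from 0.01 to 0.831 for epithelial structure, 0.0350 to 0.609 for epithelial regulators, 0.0450 to 0.979 for gut mesenchyme, 0.0450 to 0.639 for pancreas and 0.01 to 0.313 for Hox groups 9 to 13. Adjusting the ratio for GC content gave 0.13 for epithelial structure (adjusted permutation p = 0.0300) and 0.09 for Hox groups 9 to 13 (adjusted permutation p = 0.201). Away from promoters, an alternative added after the data were seen, epithelial structure had 0.21 (adjusted permutation p = 0.0250) and Hox groups 9 to 13 had 0.14 (adjusted permutation p = 0.117).

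At single promoter regions that were shared and of above-median signal, the replicates differed little. Of 11298 shared promoter regions of above-median signal, 10695 lay at a start site of a coding gene. Among these 10695 the centred log2 ratio had a median of -0.15 and an SD of 0.193, and 2 regions differed by more than 1. These were the promoters of Fam102b at -1.07 (chromosome 3, 109027481 to 109027840; signal 1.33 and 3.22) and of the glycosyltransferase gene Galnt2 at -1.01 (chromosome 8, 124231181 to 124231460). Zbtb2 at -0.99, Rufy3 at -0.93 and Tarbp1 at -0.84 followed, and the largest ratios in the other direction were those of Rims3 at 0.67, Cdk5rap3 at 0.64, Hnrnpll at 0.63, Golph3l at 0.62 and Gng8 at 0.60. With 1 library per replicate these ratios have no test. Promoters with a peak in 1 replicate only, 348 genes in replicate 1 and 349 in replicate 2, are outside this measure. The highest promoter signal of a gene can also differ more, as at Hoxa10 (1.11 and 3.40).

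Transcription factor motifs in 150 bp windows at distal peaks were compared with flanking windows 2 kb away. The motif of CTCF, which organises chromatin loops, occurred in 3.34 ± 1.07% of distal peaks, 71.9 ± 5.62 times as often as in flanks. The motif of REST, a repressor of neuronal genes, was found in 191 replicate 1 peaks with 0 matches in flanks and in 192 replicate 2 peaks with 2 matches in flanks, so no mean fold is given. The motif of NRF1, a regulator of mitochondrial genes, was 7.91 ± 0.195 times as frequent as in flanks, that of NFI 5.76 ± 1.91 times, KLF/SP 5.36 ± 0.820 times and RFX 4.61 ± 0.991 times. The NRF1 and RFX folds rest on few flank windows with a match, 11 and 17 in the replicate with fewer. The intestinal epithelial factor HNF4 had a fold of 1.31 ± 0.0313. Folds below 1 were found for CDX (0.779 ± 0.0275), FOX (0.738 ± 0.0199), GATA (0.684 ± 0.00308), the TAATTA homeobox motif (0.477 ± 0.0114), MEF2 (0.349 ± 0.0204) and PHOX2 (0.344 ± 0.0234), and each of these turned above 1 against random windows matched on GC content: CDX 1.42, FOX 1.36, GATA 1.103, TAATTA 1.299, MEF2 1.12 and PHOX2 1.64. Against the same windows the fold was 2.75 for NRF1, 3.97 for NFI, 2.61 for KLF/SP, 2.95 for RFX and 1.64 for HNF4. The CTCF fold ran from 37.6 ± 4.02 in 300 bp windows to 250.1 ± 24.1 in the strongest 50000 peaks. Against the reversed consensus it was 606 ± 319, which is not a stable fold. The reversed string holds a CpG, which the consensus does not, and had 25 matches in all peaks of the replicate with fewer. Distal peak windows had a GC content of 50.03% and 51.7% and flanks 43.6% and 44.4%.

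Footprints, short stretches protected from cleavage as called by the authors, numbered 378722 in replicate 1 and 406063 in replicate 2. CTCF matches in peaks lay in a footprint in 86.4 ± 2.80% of cases, 9.57 ± 2.08 times the share of peak bases in footprints. For the reversed consensus, with 25 matches in the replicate with fewer, the percentage was 9.56 ± 2.20%. The share was 95.2 ± 0.908% for REST, 82.5 ± 10.4% for NRF1, 64.1 ± 6.38% for KLF/SP (46.1 ± 4.54% for its reversed consensus), 56.5 ± 6.61% for RFX and 44.1 ± 11.8% for NFI (17.0 ± 1.86% for its reversed consensus). For HNF4 it was 8.59 ± 1.80% (2.69 ± 0.593% for its reversed consensus), for CDX 5.83 ± 0.667% (4.94 ± 1.94%), for GATA 4.41 ± 1.06% (4.64 ± 1.54%) and for FOX 2.86 ± 0.371% (4.88 ± 1.0997%). For MEF2 it was 4.45 ± 1.76%, for PHOX2 6.69 ± 2.17% and for TAATTA 3.79 ± 1.63%. Footprints covered 9.28 ± 2.31% of peak bases, and 84.4 ± 1.34% of them lay in peaks. A promoter peak held 4.05 footprints in replicate 1 and 4.96 in replicate 2, and a distal peak 1.19 and 1.74. Of replicate 1 footprints 40.8% overlapped a replicate 2 footprint, and 36.6% of replicate 2 footprints overlapped a replicate 1 footprint.

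**Figure D3:**
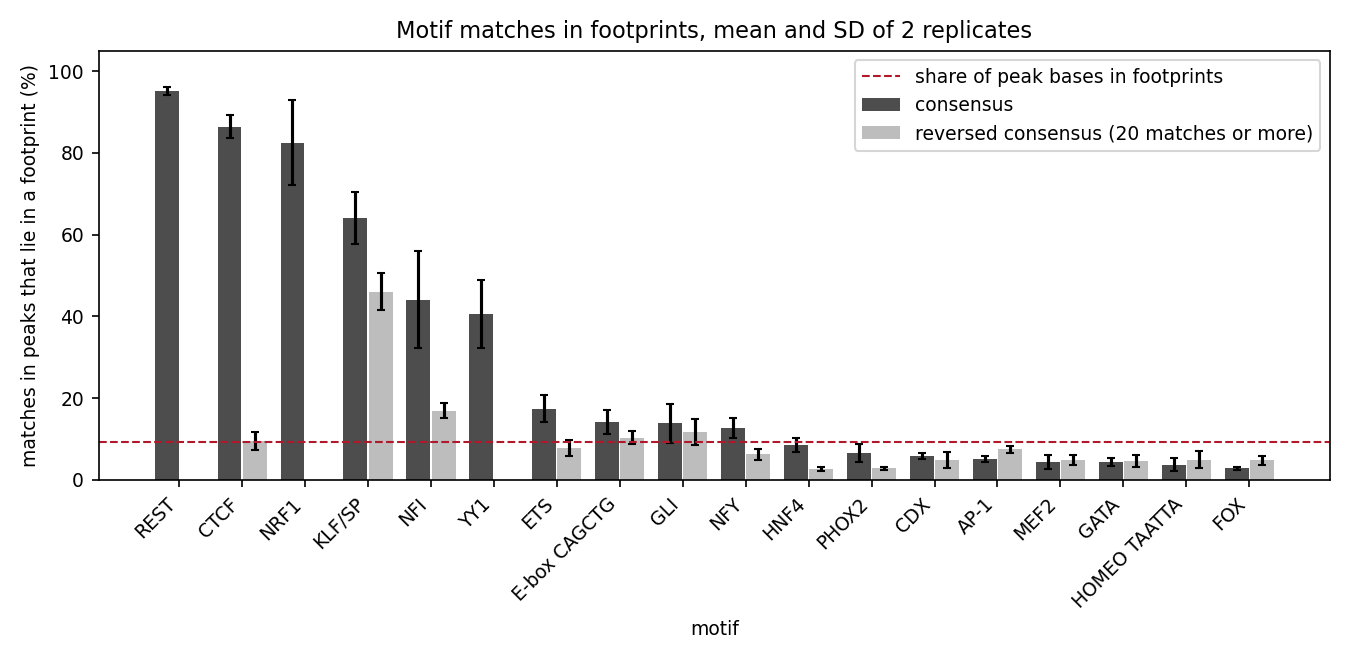
Percentage of motif matches in peaks that lie in a footprint (mean and SD of 2 replicates) for the consensus and, where it had at least 20 matches, the reversed consensus; the dashed line is the share of peak bases in footprints, 9.28%. REST and CTCF stand at 95.2% and 86.4%, and GATA and FOX at 4.41% and 2.86%, below the line.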

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

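The signal floor of 0.25, the GC adjustment, the exclusion of promoters from the replicate difference and the CpG matching were alternatives chosen after seeing the data. Over the 25 lists, the promoter test kept its side of the threshold in 186 of 200 comparisons with an alternative, the distal test in 241 of 275 and the replicate difference in 141 of 150. Direction was kept as well in 170, 229 and 117 of these. In the other 16, 12 and 24 it changed without a call under either setting. These totals include the lists without a call, the larger part in each test. Among lists called as reported, the call was lost in 1, 22 and 5 comparisons. The replicate difference had 2 called lists with 6 alternatives each. Among the other lists a call was gained in 13, 12 and 3 comparisons, and in 1 more of the replicate difference it came with a change of direction. Where results changed, the cause was not tested. The mean number of peaks was 111728 in the shorter list and 50000 by construction among the strongest. The mean shared percentage became 89.3 among the strongest peaks, 72.4 above the signal floor and 35.8 with an overlap of at least 50% of both peaks. Spearman's rho was 0.967 in the shorter list, 0.954 in the list from the other alignments, 0.952 among the strongest peaks, 0.947 above the signal floor and 0.967 with the 50% overlap. The promoter percentage was 21.9 within 1000 bp, 31.6 within 2500 bp and 20.7 above the signal floor. Lists higher at promoters numbered 2 in the shorter list, 3 among the strongest peaks, 2 with the 50% overlap and 2 within 1000 bp, against 1 as reported, and lists lower numbered 6 in the shorter list and 5 among the strongest peaks, against 2. Lists higher in distal regions numbered 7 without matching of random lists, against 11, and 9 with CpG matching. Lists higher in replicate 1 numbered 1 after GC adjustment and 1 away from promoters, against 2, and gut mesenchyme turned from -0.03 to 0.43 with hotspot values. Hox promoters covered in both replicates numbered 18 with the 50% overlap and 35 within 1000 bp of a start site, against 32. The CTCF fold at distal peaks was 137 in the shorter list, 250.1 among the strongest peaks, 37.6 in 300 bp windows, 50.7 against GC-matched windows and 101 above the signal floor. It was 606 against the reversed consensus, which had few matches. Folds that turned from below to above 1 against GC-matched windows and against the reversed consensus were TAATTA (1.299 and 1.04), MEF2 (1.12 and 1.35), PHOX2 (1.64 and 1.20), CDX (1.42 and 1.54) and GATA (1.103 and 1.33), and FOX turned against GC-matched windows only (1.36). The best-scoring part of the footprints was not run as an alternative, because all footprints carry the value 0.01. Without absolute depth it cannot be said which missing peaks lay below the reach of each library. No paired analysis was possible because there is 1 group.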

Other observations

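The test of the share of epithelium was chosen after the results were seen, and the values in the next 3 paragraphs were selected after the data were seen.

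Promoter peaks carried motifs of general promoter factors. Their windows had a GC content of 61.0% and 62.0%, against 44.3% and 44.4% in flanks, so the fold against random windows matched on GC content is given beside the fold against flanks. The KLF/SP motif occurred in 9.18 ± 1.06% of promoter peaks, 45.2 ± 9.05 times as often as in flanks but 4.32 ± 0.0284 times as often as in matched windows. The ETS motif occurred in 9.71 ± 0.306% (4.91 ± 0.321 times against flanks, 1.65 ± 0.0857 times against matched windows) and the NFY motif, the CCAAT box, in 4.50 ± 0.256% (3.34 ± 0.351 and 3.58 ± 0.454 times). The EBF motif was 2.04 ± 0.00917 times as frequent as in flanks and 0.982 ± 0.0335 times as frequent as in matched windows. The NRF1 motif occurred in 0.544 ± 0.0727% of promoter peaks, the YY1 motif in 0.403 ± 0.0416% and the RFX motif in 0.103 ± 0.00360%, with too few matches in flanks for a stable fold. CTCF was 15.9 ± 1.05 times as frequent as in flanks at promoters, against 71.9 ± 5.62 times at distal peaks, and 17.1 ± 2.93 against 50.7 ± 11.3 times with matched windows.

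Shared and private distal peaks differed in motif content. CTCF was 124 ± 7.82 times as frequent as in flanks in shared distal peaks and 10.2 ± 3.88 times in private ones. REST occurred in 0.272% of shared distal windows and 0.00561% of private ones. A footprint was present in 80.8% and 83.2% of shared peaks and in 33.3% and 48.5% of private peaks. Chromosome X had 23.9 and 21.1 peaks per Mb in the 2 replicates, and chromosome 11 had 103 and 83.8.

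Replicate 1 had 208181 peaks and replicate 2 had 151122, while at a signal of 0.25 or more they had 118364 and 124337. At shared regions the median log2 ratio of replicate 1 to replicate 2 signal was -0.21, so a floor of 0.25 is looser in replicate 2 and these counts are not on 1 scale. The steep peaks, those with a very low false discovery rate for their signal, had a median slope of 62.9 and 57.0, against 7.07 and 7.74 for the others. Steep peaks numbered 86862 in replicate 1 and 17829 in replicate 2, and the others 121319 and 133293. The highest of the peaks' lowest false discovery rates was 0.0499 in both replicates, which argues against a different cut on this rate. No other explanation of the difference in number was tested. Depth, other settings of the authors' calling and weak sites below the reach of replicate 2 stay open, because the sources used here give neither depth nor settings.

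With peak signal, epithelial structure genes were higher in replicate 1, with a median log2 ratio of 0.15. With hotspot values this call was lost (0.03, adjusted permutation p = 0.831). After adjustment of the peak signal ratio for GC content the median was 0.13, outside the central 95% of random lists (-0.07 to 0.08, permutation test, adjusted p = 0.0300), which argues against GC content as the whole cause. The other 4 epithelial lists (57 genes, median 0.08) exceeded 7 lists of other gut wall cell types (79 genes, -0.02) by 0.092 (random splits -0.06 to 0.06, permutation p = 0.0008). With hotspot values the difference was -0.08 (random splits -0.24 to 0.22, permutation p = 0.416), inside the range of random splits, so a larger share of epithelium in replicate 1 stays open. So does more posterior gut, which was not tested: Hox groups 9 to 13 and 1 to 4 stood at 0.13 and -0.04 with peak signal, at 0.14 and -0.06 away from promoters and at 0.23 and 0.18 with hotspot values.

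Brain genes such as Pax6 and Emx2 had many distal regions in this gut tissue, 4.17 times those of random lists. Above a signal of 0.25 the ratio was 4.35 (random lists 0.387 to 1.89, permutation test, adjusted p = 0.00125), which argues against the low-signal peaks called in runs. With random lists also matched on CpG-dense sequence the ratio fell to 2.17 (random lists 0.565 to 1.55, permutation test, adjusted p = 0.00625). The matching used 5 classes of CpG-dense bins within each decile of length. Brain windows held a mean of 8.9 such bins against 1.66 for all coding genes, and the bins of the random lists were not measured. CpG-dense sequence therefore stays open as a part or the whole of the cause. Several members are developmental regulators, and no biological explanation was tested.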
